A study of Mus musculus with 8 samples.

How the data were processed

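RNA was taken from snap-frozen mouse liver, selected for poly-A tails and made into strand-specific libraries, per the labels' protocols. The data are 1 deposited table of 20894 genes by 8 libraries that holds estimated counts as whole numbers, not normalized by the authors. The submitters' processing notes name Salmon 1.2.1, a tool that estimates transcript abundance, and the builds GRCm38 and mm10, with no role for either. The annotation release, the rounding and the way transcripts were combined into genes are not given in the sources used here. A gene symbol was found for 20817 of the Ensembl identifiers in a GENCODE M21 name table, and 5422 genes had 0 counts in every library. Coordinates are from GENCODE M21 on GRCm38, counted from 1.

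The table gives few counts to some genes that liver and most other tissues express strongly: Actb had 0 to 29 counts in a library, Rpl3 0 to 3, Acadm 0 to 24 and Acaa2 0 to 3 (chosen after their values were seen). Such genes have several annotated coding transcripts, and the closing section tests whether the gene values hold part of the transcripts. CPM levels, folds of genes with several coding transcripts and library totals are to be read with that limit. GENCODE M21 gives 1 coding transcript for Fgf21, Slc10a2, Cyp4a14, Vnn1 and Acaa1b, 2 for Polr2g and Cyp4a10, 5 for Hsd3b3, 6 for Cd36 and 7 for Irf3.

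Columns were assigned to samples by library name. A POLR2G column whose number the labels do not list was used as a POLR2G library without a replicate number. The design is 4 POLR2G against 4 GFP control libraries. The 12 pairs of libraries within a group differed by far more than sampling noise (chi-square per degree of freedom from 13.7 to 138), so none was counted as a duplicate. Groups, lists, tests and all alternatives but those named below were fixed before the data were examined.

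The main test was the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3; TMM scaling; filterByExpr with a minimum count of 10 and a minimum total of 15; group as the only term; two-sided) over 10390 genes, with Benjamini-Hochberg adjustment and a threshold of 0.05. Its biological coefficient of variation was 0.248. The SE of a log2 fold change is its size divided by the square root of the quasi-likelihood F. Single values were compared with exact two-sided permutation tests over all 70 arrangements of the libraries, on log2 CPM with a prior count of 2 for genes, which cannot give p below 0.0286. In all, 37 gene lists covered liver metabolism, stress and immune programs, RNA polymerase subunits, sex-biased and zonated genes, technical signs and markers of other cell types. The 32 lists with at least 5 tested genes were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists. Beside it stood camera with an estimated correlation and fry, read by its directional test unless its mixed test is named. The count of members past the threshold is given over all genes and adjusted over the list alone.

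Named genes follow a fixed rule. It takes Polr2g, Fgf21 and Irf3 always, and all genes past the threshold if fewer than 20 pass, as here. If more pass, it takes the 10 largest and 10 smallest log2 fold changes with a mean log2 CPM of at least 1 and the groups apart, and the 5 smallest p in each direction, leaving out unnamed models and pseudogenes. In each list it takes up to 4 called members or, with none called, the 2 members with the smallest p, as values. Some genes that the rule takes are not used here. The PPARA members other than Cd36, and Tox and Cyp2c69, were chosen after their values were seen.

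The steps were tested on simulated data with the means, library sizes and spread of these libraries and 200 of 10390 genes changed. For this comparison edgeR recovered 28% of 1.5-fold, 66% of 2-fold, 86% of 4-fold and 96% of 8-fold changes, with 10 false among 167 calls. DESeq2 1.42.0 recovered 40%, 76%, 86% and 98% of them, with 34 false among 207 calls, and 3 of 3 shifted lists were called with 0 others. The simulated genes varied independently of each other. In the real libraries the estimated correlation within a list was 0.527 for male-biased genes and 0.851 for mitochondrial transcripts. The simulation therefore cannot show how often lists with correlated members are called falsely. Alternatives changed 1 choice at a time, except that the replicate block also left out the 2 libraries without a shared number. They were RLE, upper quartile or no composition scaling, DESeq2, limma-voom and a robust dispersion fit. Further ones were no or a stricter low-count filter (1 CPM in 4 libraries), Polr2g or the 20 most abundant genes left out of library sizes, a test against 1.2-fold (glmTreat), 1 surrogate variable (sva 3.50.0), the replicate number as a block, and each library left out. Chosen after seeing the data were the fit of the same 6 libraries without the block, the Mup share as a covariate and a fit of only genes with 1 coding transcript. DESeq2 gave no adjusted p (NA) for 2621 genes, Fgf21 among them.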

Results

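Gene expression was measured by strand-specific poly-A RNA sequencing in the livers of wild-type mice that had received an adeno-associated virus of serotype AAV8, a vector that enters liver cells efficiently. The animals were killed after a fast during the day. The TBG promoter, taken from the thyroxine-binding globulin gene and active mainly in hepatocytes, drove either POLR2G, a subunit of RNA polymerase II, or green fluorescent protein (GFP) as the control. There were 4 libraries per group. Total estimated counts in the table were 18865284, 16286695, 14159056 and 18154725 in GFP control replicates 1 to 4. The POLR2G libraries held 22165491 in replicate 1, 17304911 in replicate 3, 18381979 in replicate 4 and 16362899 in the unnumbered POLR2G library, whose column number the labels do not list. Totals did not differ between the groups beyond their spread (n = 4 each, exact permutation p = 0.371). The labels name mice but tie no library to an animal, so p-values measure the spread between these libraries. Values below are CPM (counts scaled to a common library size with TMM factors) as mean ± SD over the 4 libraries of a group. Log2 fold changes are POLR2G against GFP control with their standard error (SE).

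The comparison asks what extra POLR2G in hepatocytes does to liver gene expression in the fasted state. The series names Fgf21, which encodes a fasting-induced liver hormone, and metabolic genes as its readouts. Polr2g itself (ENSMUSG00000071662; GRCm38 chromosome 19, 8793127 to 8798577, minus strand) was 176-fold higher in the POLR2G libraries. It measured 13.7 ± 1.003 CPM in the GFP control libraries and 2412 ± 154 CPM in the POLR2G libraries (log2 fold change 7.46, SE 0.102, edgeR adjusted p = 3.23e-10). Counts were 213 to 258 in the 4 GFP control libraries and 38649 to 54553 in the 4 POLR2G libraries, so every library matched its group. Reads from the vector count toward this value only where its sequence matches the annotated mouse transcript. Endogenous and vector transcripts were not separated.

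Fgf21 (ENSMUSG00000030827; chromosome 7, 45613886 to 45615490, minus strand) was 2.70-fold lower in the POLR2G libraries, at 2.34 ± 0.584 CPM in the GFP control libraries and 0.864 ± 0.379 CPM in the POLR2G libraries (log2 fold change −1.44, SE 0.381). All 4 POLR2G libraries, with 10, 11, 17 and 23 counts, lay below all 4 GFP control libraries, with 33, 34, 41 and 52 counts. The exact two-sided permutation test of log2 CPM gave p = 0.0286, the smallest that 4 against 4 libraries allow. Over all 10390 genes tested the edgeR adjusted p was 0.344, and it was 0.00621 when adjusted over the 3 genes of the series title alone. Irf3 (ENSMUSG00000003184; chromosome 7, 44997648 to 45002848, plus strand), encodes a transcription factor of innate immunity and did not change over all genes. It measured 13.4 ± 2.87 CPM in the GFP control libraries and 10.3 ± 1.07 CPM in the POLR2G libraries (log2 fold change −0.38, SE 0.160, edgeR adjusted p = 0.565). The exact permutation p was 0.0571, and the edgeR p adjusted over the title genes alone 0.0402. GFP control replicate 1 stood apart for Irf3 at 17.6 CPM. All 3 title genes passed when adjusted over the list alone. The title can have been written from these samples, so that count is not independent evidence, and the few counts of Fgf21 limit the precision of its fold.

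Across all genes tested, 4 changed (2 higher and 2 lower, edgeR adjusted p under 0.05). Besides Polr2g, Hsd3b3 (ENSMUSG00000062410; chromosome 3, 98741523 to 98763127, minus strand), a hydroxysteroid dehydrogenase, rose 1.57-fold from 195 ± 7.08 to 306 ± 21.5 CPM (log2 fold change 0.65, SE 0.0690, adjusted p = 0.0227). Slc10a2 (ENSMUSG00000023073; chromosome 8, 5083219 to 5105351, minus strand), the apical sodium-dependent bile acid transporter, fell 2.05-fold from 61.8 ± 10.2 to 30.1 ± 2.30 CPM (log2 fold change −1.04, SE 0.120, adjusted p = 0.0306). Cd36 (ENSMUSG00000002944; chromosome 5, 17781690 to 17888801, minus strand), a fatty acid transporter, fell 1.75-fold from 39.6 ± 3.57 to 22.7 ± 2.44 CPM (log2 fold change −0.80, SE 0.101, adjusted p = 0.0481). For these 4 genes all libraries of one group lay above all of the other, as for 572 genes in total (5.51%, where chance gives 2.86%). At an unadjusted p under 0.05 edgeR gave 862 genes, 436 higher and 426 lower, with 519.5 expected by chance. DESeq2, the other count test, called 140 genes (76 higher and 64 lower), the 4 edgeR genes among them, and limma-voom called 3. Upper quartile scaling called 2 genes higher and 1 lower, and scaling by library totals only called Polr2g alone. The count fell to 1 without POLR2G replicate 1 or replicate 4 and to 2 without GFP control replicate 2 or the unnumbered POLR2G library. Of the 8 fits that left out 1 library, Hsd3b3 and Slc10a2 passed in 3 each and Cd36 in 1. Hsd3b3 belongs to a family of near-identical genes among which estimated counts can be split, so its value is uncertain. Polr2g, Irf3, Hsd3b3 and Cd36 have several annotated coding transcripts, and it is open whether their values cover all of them.

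**Figure D1:**
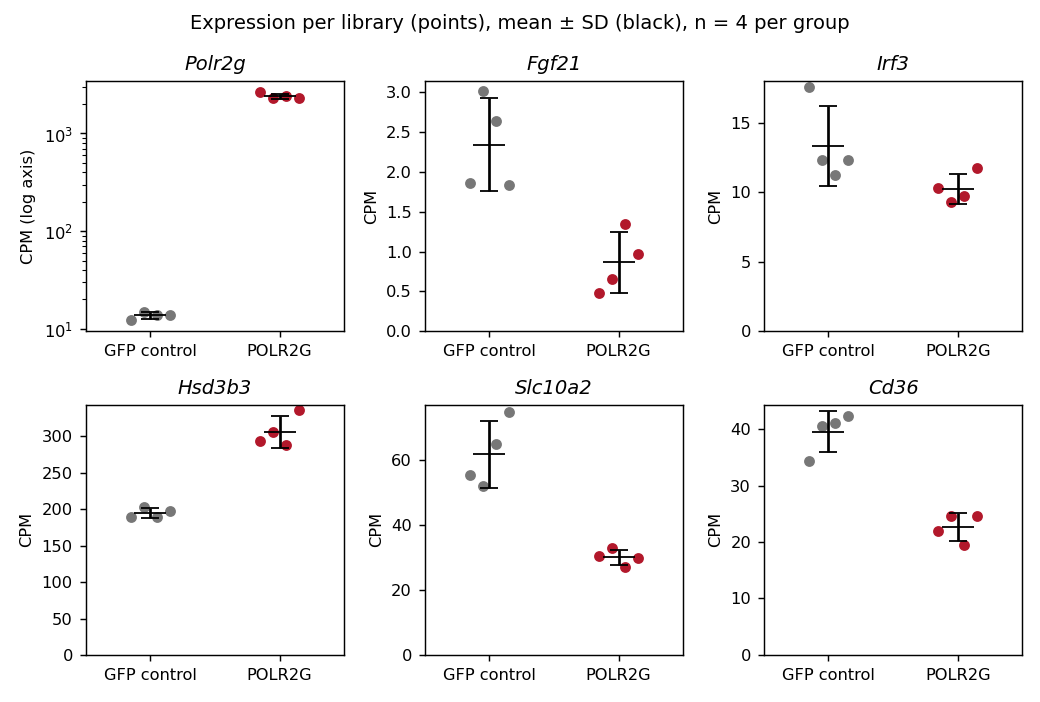
Expression of the 3 title genes and the 3 other changed genes in each library, with CPM on the vertical axis (a log axis for Polr2g only) and the 2 groups on the horizontal axis. Points are libraries and black marks are the mean ± SD of 4 libraries; Polr2g rises from 13.7 to 2412 CPM, Fgf21 goes from 2.34 to 0.864 CPM, and the Irf3 points of the groups overlap.

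PPARA is a nuclear receptor that drives the liver's response to fasting. A list of fatty acid oxidation genes and other known PPARA targets, such as Cd36, Acot1 and Pdk4, was lower in the POLR2G libraries. Of its 36 genes, Acadm, Acads, Acaa2, Etfdh and Angptl4 were not tested. Of the 31 members tested 26 had a lower mean and 5 a higher one (median log2 fold change −0.15, mean −0.69, camera adjusted p = 9.84e-16). Cd36 passed over all genes, and 13 members passed when adjusted over the list alone, all of them lower. The microsomal omega-hydroxylase gene Cyp4a14 fell 20.9-fold on that adjustment, from 198 ± 110.4 to 9.56 ± 6.79 CPM. Cyp4a31 fell 5.31-fold, from 5.97 ± 2.23 to 1.12 ± 0.527 CPM, and Cyp4a10 2.88-fold, from 309 ± 54.5 to 107 ± 44.1 CPM. The acyl-CoA thioesterase genes Acot1 (2.17-fold, from 53.3 ± 9.66 to 24.6 ± 5.44 CPM), Acot3 (4.85-fold), Acot4 (1.68-fold) and Acot2 (1.71-fold) fell too. So did Vnn1, a pantetheinase (2.03-fold, from 45.6 ± 14.7 to 22.5 ± 2.09 CPM), and Pdk4, a kinase that inhibits pyruvate dehydrogenase (2.39-fold, from 7.12 ± 3.80 to 2.97 ± 0.445 CPM). The peroxisomal thiolase genes Acaa1b (1.67-fold, from 917 ± 259 to 549.8 ± 87.3 CPM) and Acaa1a (3.93-fold) and the carnitine acetyltransferase gene Crat (2.56-fold) complete the 13. All of them beyond Cd36 are named after their values were seen. Among members that did not pass, Cpt1a had a log2 fold change of −0.15 (SE 0.108), Hadha −0.0959 (SE 0.0741) and Acadl −0.064 (SE 0.0657), also chosen after the values were seen. Other oxidation genes hardly differed, such as Hadh (−0.027, SE 0.0727) and Decr1 (−0.060, SE 0.106). The 5 members with a higher mean were Cpt2 (0.23), Slc27a2 (0.17), Creb3l3 (0.046), Acadvl (0.0080) and Eci1 (0.0080), and none passed. The fall of the list thus rests mainly on the 13 members that passed, several of which are not oxidation enzymes. It was not even across the pathway and does not show a fall of fatty acid oxidation genes as a whole.

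Cyp4a and Acot members, which share reads with near-identical copies, were also summed. The sum does not depend on how estimated counts were split among them, if the table holds all of their transcripts. The 4 Cyp4a genes of the list together measured 543 ± 166 CPM in the GFP control and 145 ± 54.3 CPM in the POLR2G libraries, 3.80-fold lower on the log scale (SD, n = 4 per group, exact permutation p = 0.0286). Acot1 to Acot4 together measured 224 ± 51.1 and 116 ± 30.0 CPM, 1.94-fold lower (exact permutation p = 0.0286). The mixed test of fry, which ignores direction, passed 8 of the 32 lists. In it RNA polymerase II subunits had a smaller adjusted p (fry mixed, 1.06e-06) than the PPARA list (2.42e-05). The PPARA list is the one list of 32 that also passed camera with an estimated correlation between genes (adjusted p = 0.0321) and the directional test of fry (adjusted p = 0.00664). Its score, the mean log2 CPM of its members minus the GFP control mean, was −0.68 ± 0.113 in the POLR2G libraries against an SD of 0.0692 in the GFP control libraries (n = 4 each, exact permutation p = 0.0286). Without the Cyp4a, Acot and Acaa1 members the camera p of the other 21 was 1.57e-04, and 0.0906 with an estimated correlation. The table holds only low counts for some list members that liver expresses strongly, Plin2 (at most 30 in a library), Cpt2 (at most 31) and Acaa1a (at most 31), and it is open whether these values cover all of the genes' transcripts.

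**Figure D2:**
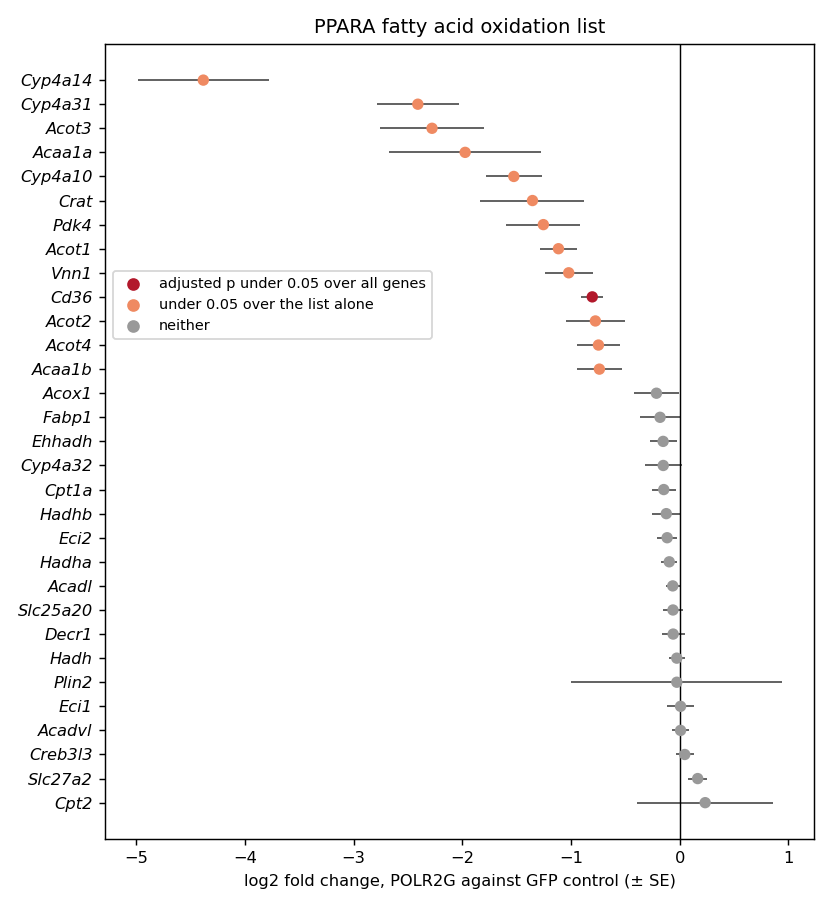
Log2 fold changes (horizontal axis, POLR2G against GFP control, bars are SE) of the 31 tested members of the PPARA fatty acid oxidation list, one gene per line. Dark red is Cd36, which passed over all genes, orange marks the 12 other members that passed over the list alone, all left of 0, and grey marks members that passed neither.

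Of the other 31 lists with at least 5 tested genes, 5 passed camera with its preset correlation, and none of the 5 passed with an estimated one. Cholesterol synthesis genes were lower (17 of 19 with a lower mean, median log2 fold change −0.25, adjusted p = 1.79e-06; adjusted p = 0.496 with an estimated correlation). Its member Idi1 (−0.34, SE 0.102), an isoprenoid enzyme gene, did not pass over the list alone. Lipogenesis genes were lower as a list (12 of 15, median −0.27, adjusted p = 0.00897, and 0.514 with an estimated correlation). Without GFP control replicate 4 the median was −0.11 (adjusted p = 0.270 with the preset correlation). The 2 members that passed over the list alone, Fads2 (1.28-fold lower, from 1357 ± 99.6 to 1059 ± 96.0 CPM) and Fads1 (1.204-fold lower, from 717 ± 52.8 to 596 ± 30.7 CPM), encode fatty acid desaturases. Genes with male-biased liver expression were higher (11 of 14, median 0.45, adjusted p = 7.50e-06; adjusted p = 0.496 with an estimated correlation). The shift goes in part with GFP control replicate 3, whose list score was −0.67, against 0.076 to 0.42 in the other 3 GFP control and 0.35 to 0.56 in the POLR2G libraries, and which also had the lowest Mup share (6.89%). Without it the median was 0.26 (adjusted p = 0.0122). Serpina1e, an antitrypsin gene that shares reads with its copies, passed over the list alone (1.60-fold higher, from 10590 ± 1685 to 16947 ± 2179 CPM), and Nudt7 (0.58, SE 0.181) did not. Immediate early genes were higher (11 of 13, median 0.42, adjusted p = 3.21e-04; adjusted p = 0.496 with an estimated correlation), with Dusp1, a phosphatase of MAP kinases (2.72-fold, from 20 ± 3.07 to 54.4 ± 17.4 CPM), and Myc, a growth-related transcription factor (3.01-fold, from 8.08 ± 5.19 to 24.4 ± 9.13 CPM), past the threshold over the list alone. The score was highest in POLR2G replicate 4, at 1.15, against 0.25 to 0.57 in the other 3 POLR2G libraries, and without it the median was 0.18 (adjusted p = 0.00244). Oxidative phosphorylation genes were slightly higher (33 of 40, median 0.076, adjusted p = 0.00497; adjusted p = 0.752 with an estimated correlation, and 0.123 with the preset one without GFP control replicate 3). Its leading members Ndufb9 (0.16, SE 0.0604) and Ndufa4 (0.16, SE 0.0636) did not pass over the list alone. With the preset correlation, 23 of the 35 ways to split the 8 libraries into 4 and 4 called at least 6 lists. Among genes with 1 annotated coding transcript the PPARA and cholesterol lists passed, while oxidative phosphorylation (adjusted p = 0.0751), male-biased (0.0751) and immediate early genes (0.133) did not, and too few lipogenesis genes were left to test.

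**Figure D3:**
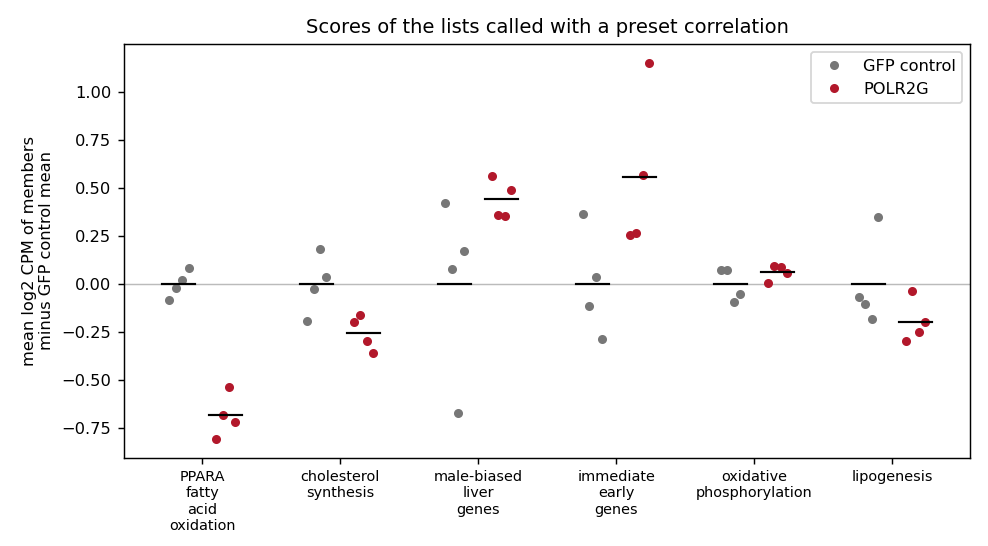
Scores of the 6 lists called with a preset correlation, as the mean log2 CPM of the members minus the GFP control mean (vertical axis), for each library. Points are libraries and black lines group means of 4 libraries; the PPARA scores of the POLR2G libraries lie between −0.81 and −0.53, all below the GFP control libraries, while the groups overlap in the other 5 lists.

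No other list passed camera. Among metabolic lists, gluconeogenesis and fasting response had 12 of 14 members with a lower mean (median −0.26, adjusted p = 0.0609), led by Ppargc1a (−0.48, SE 0.134), a coactivator of fasting genes, and Sesn1 (−0.31, SE 0.124). Ketogenesis (median −0.0465, adjusted p = 0.425) included Slc16a1 (−0.26, SE 0.0803), a transporter gene for ketone bodies and lactate. Bile acid synthesis and transport (median 0.029, adjusted p = 0.425) was led by Amacr (0.22, SE 0.0814) and Slc27a5 (0.27, SE 0.137). In urea cycle and amino acid catabolism (median 0.040, adjusted p = 0.117), 3 of 25 members passed over the list alone and were higher. They are Gpt, an alanine aminotransferase (1.27-fold, from 278 ± 12.6 to 353 ± 5.30 CPM), Otc, a urea cycle enzyme (1.497-fold, from 14.2 ± 0.899 to 21.2 ± 2.64 CPM), and Hal, the histidine ammonia-lyase (1.25-fold, from 256 ± 16.9 to 319 ± 15.5 CPM). Drug metabolism (median −0.0482, adjusted p = 0.506) had a negative median with a positive mean and test direction, and Cyp2c50 (0.33, SE 0.0887) and Cyp2c54 (0.54, SE 0.146) led it. The hepatokine list (median 0.0522, adjusted p = 0.487) had a mean of −0.0021, against its median and test, with Lcat (0.23, SE 0.0783) and Igf1 (0.25, SE 0.1) in front.

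Female-biased liver genes (median −0.82, adjusted p = 0.143) had 6 tested members. Of these Cyp17a1, a steroid hydroxylase (2.52-fold lower, from 20.3 ± 9.40 to 8.06 ± 2.18 CPM), and Tox (−0.69) were lower over the list alone and Cyp2c69 (0.64) higher, the last 2 chosen after their values were seen. GFP control replicate 3 had the highest score of this list, at 0.84, against −0.54 to −0.061 in the other 3 GFP control and −0.97 to −0.57 in the POLR2G libraries. Without that library the median was −0.51 (camera adjusted p = 0.182). Markers of pericentral hepatocytes (median 0.062, adjusted p = 0.578) went both ways, with the ammonium transporter gene Rhbg 1.84-fold higher (from 9.99 ± 2.001 to 18.4 ± 2.43 CPM) and the amino acid transporter gene Slc1a4 1.95-fold lower (from 3.31 ± 0.904 to 1.69 ± 0.288 CPM) over the list alone. Periportal markers (median −0.031, adjusted p = 0.580) had a negative median and mean with a test direction of up. Hal passed over the list alone and Cyp2f2 (0.20, SE 0.0673) did not.

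The other subunits of RNA polymerase II (median 0.101, adjusted p = 0.117) included Polr2l, 1.36-fold higher (from 32.6 ± 1.46 to 44.4 ± 2.28 CPM) over the list alone, and Polr2b (0.22, SE 0.0787), which did not pass. Subunits of RNA polymerases I and III (median 0.0524, adjusted p = 0.790) had a mean of −0.073, opposite to the median and the test, and included Twistnb (−0.16, SE 0.0877). Interferon-stimulated genes (median −0.13, adjusted p = 0.506), many of them downstream of IRF3 in infected cells, had no member past the threshold over the list alone (Oas3 (−0.50, SE 0.263), Irf7 (0.30, SE 0.166)). In the acute phase list (median −0.024, adjusted p = 0.697), whose median was negative and whose mean and test were positive, Socs3, a feedback inhibitor of cytokine signalling, was 2.01-fold higher over the list alone (from 5.21 ± 0.499 to 10.5 ± 2.61 CPM), and Fga (0.45, SE 0.137) did not pass. The integrated stress response (median −0.083, adjusted p = 0.506) had Vldlr (−2.06, SE 0.583) and Chac1 (0.82, SE 0.389), and the unfolded protein response (median −0.017, adjusted p = 0.811) Xbp1 (0.44, SE 0.270) and Hyou1 (−0.40, SE 0.269), as leading members. NRF2 targets (median 0.026, adjusted p = 0.781) had a mean of −0.091, opposite to the median and the test, with Nqo1 (0.26, SE 0.274) and Abcc4 (−1.74, SE 1.48). The circadian clock (median 0.0076, adjusted p = 0.811), with a positive median but a negative mean and test, included Nfil3 (−0.34, SE 0.149). For p53 targets (median −0.020, adjusted p = 0.425) the leading members were Plk2 (−0.40, SE 0.153) and Sesn1. They were Top2a (−0.31, SE 0.350) and Ccna2 (−0.31, SE 0.386) for proliferation (median −0.093, adjusted p = 0.578), and for heat shock (median −0.11, adjusted p = 0.0585) Chordc1 (−0.45, SE 0.129) and Hspa1a (−0.9999, SE 0.384).

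Markers of other liver cell types did not pass in any list. Macrophage and Kupffer cell markers (median 0.20, adjusted p = 0.102) included Lyz2 (0.61, SE 0.250) and Csf1r (−0.52, SE 0.275), and T and NK cell markers (median 0.24, adjusted p = 0.425) Ccl5 (0.82, SE 0.475) and Cd4 (0.37, SE 0.326). Endothelial markers (median 0.058, adjusted p = 0.994), with a mean of −0.041 against the median and the test, included Lyve1 (−0.85, SE 0.277) and Oit3 (−0.22, SE 0.135). Stellate cell and fibroblast markers (median 0.11, adjusted p = 0.506) included Ecm1 (0.29, SE 0.217) and Des (0.29, SE 0.260), and red blood cell genes (median 0.15, adjusted p = 0.243) Alas2 (0.44, SE 0.208) and Hba-a1 (0.20, SE 0.290). Lists with fewer than 5 tested genes have no set test. Neutrophil markers were Cxcr2 (−0.52, SE 0.273) and Csf3r (0.40, SE 0.350), and the 4 cholangiocyte markers (median 0.28) included Spp1 (0.70, SE 0.547). B and plasma cells had Jchain (−0.51, SE 0.417), adipocytes Fabp4 (−0.27, SE 0.207) and exocrine pancreas Cela2a (0.20, SE 0.539). Transcripts of the mitochondrial genome (median 0.039, adjusted p = 0.506), with mt-Co1 (0.088, SE 0.0982) and mt-Nd4 (0.093, SE 0.104), made up 12.2% ± 1.25 of counts in the GFP control and 12.05% ± 0.412 in the POLR2G libraries (SD, n = 4 each, exact permutation p = 0.914). Major urinary protein (Mup) genes took 10.6% ± 3.87 and 14.7% ± 2.37 (exact permutation p = 0.114), and the 20 most abundant genes 36.3% ± 2.01 and 37.5% ± 1.41 (exact permutation p = 0.371).

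Over all tested genes the first principal component of log2 CPM held 18.1% of the variance and separated the groups (exact permutation p = 0.0286, the smallest possible). The second held 16.5% (exact permutation p = 0.0571) and the third 15.3% (exact permutation p = 0.943). GFP control replicate 3 lay far from the rest on the first component, at 51.4 where the other 3 GFP control libraries lay between −6.30 and 10.5 and the 4 POLR2G libraries between −18.7 and −12.7. Without Polr2g the first component gave an exact permutation p of 0.0857.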

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

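A library was listed when it stood far from the other 3 of its group by Dixon's test, on the named genes, list scores and library measures. Of 208 groups tested 14 were listed, where chance gives about 10.4, so the number is close to what chance gives.

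Irf3 was at 17.6 CPM in GFP control replicate 1 and between 11.2 and 12.3 CPM in the other 3. Oas3 reached 2.66 CPM in GFP control replicate 4 (others 2.37 to 2.39). POLR2G replicate 4 had 14.4 CPM of Socs3 (others 8.62 to 9.60). GFP control replicate 3 had 412 CPM of Cyp2c54 (others 291 to 308) and 7.29 CPM of Cxcr2 (others 4.29 to 4.41). Abcc4 was listed at 0 CPM in GFP control replicate 2, with 2.13 to 2.55 CPM in the other 3, and at 2.17 CPM in POLR2G replicate 3, with 0 in the other 3 POLR2G libraries. Nfil3 measured 25.8 CPM in GFP control replicate 1 (others 18.2 to 19.3). Nudt7 measured 259.7 CPM in POLR2G replicate 3 (others 358 to 365). Hal measured 342 CPM in POLR2G replicate 1 (others 309.7 to 313). The drug metabolism score was −0.0961 in GFP control replicate 1 (others 0.0232 to 0.0376) and −0.227 in POLR2G replicate 1 (others 0.0642 to 0.0860). The circadian clock score was 0.157 in GFP control replicate 4 (others −0.0672 to −0.0302). Mitochondrial transcripts took 11.4% of counts in POLR2G replicate 3 (12.2% to 12.3% in the other 3).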

How the results depend on the processing

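Polr2g, Fgf21 and Irf3 kept their direction and their side of the threshold in every alternative that gave them a value, with log2 fold changes of 7.38 to 7.51, −1.73 to −1.18 and −0.46 to −0.22. The PPARA list stayed lower and past the threshold in all 21 alternatives that test lists by camera (adjusted p from 1.05e-23 to 4.82e-05), and 9 to 13 members passed over the list alone with 1 library left out, with at most 1 member higher. Its median log2 fold change, −0.152 in the main fit, ranged from −0.275 without GFP control replicate 3 to −0.131 with upper quartile scaling. The count of 4 genes (2 higher, 2 lower) did not hold. DESeq2 gave 140 (76 higher, 64 lower), 1 surrogate variable 13 (7 higher, 6 lower), no filter 6 (2 higher, 4 lower), library totals only 1 (1 higher, 0 lower), glmTreat 1 (1 higher, 0 lower) and the Mup share as a covariate 1 (1 higher, 0 lower). Upper quartile scaling and limma-voom each gave 2 higher and 1 lower, and only genes with 1 coding transcript 3 (1 higher, 2 lower), from fewer genes tested. With 1 library left out there were 1 to 6 genes (1 to 3 higher, 0 to 3 lower) and 7 to 9 lists. With 28% of 1.5-fold changes recovered in simulated data, depth and spread limit the count for small changes. Large changes failed too: the edgeR adjusted p was 0.0668 for Cyp4a14 (20.9-fold lower) and 0.203 for Acot3 (4.85-fold lower). The simulated shares of recovered genes need not hold here, since edgeR made 167 calls in the simulated data and 4 in the real. For DESeq2 against edgeR the cause was not tested. List calls went from 6 to 1 with an estimated correlation, 1 with the directional test of fry and 2 with only genes of 1 coding transcript, 7 with no filter and 5 with library totals only.

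The replicate numbers of the labels pair the libraries by number only: deviations of same-numbered libraries correlated at 0.064, −0.025 and 0.036 over the 3 numbers both groups carry, and not every library correlated best with its own number. A replicate block on those 6 libraries gave 2 genes (1 higher, 1 lower) and 8 lists, and the same 6 libraries with no replicate block 1 gene (1 higher, 0 lower) and 7 lists. The log2 fold change under the replicate block was 7.51 for Polr2g, −1.26 for Fgf21 and −0.35 for Irf3.

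Some directions turned, all in lists and genes that passed in neither fit. The list values are medians, and a direction is that of the test. They were endothelial 0.077 with upper quartile scaling, endothelial 0.060 with DESeq2 and circadian clock 0.036 with no filter. Under the replicate block they were integrated stress response 0.020, circadian clock 0.11, macrophage and Kupffer cell −0.055, endothelial 0.039, red blood cell −0.101, Csf3r −0.023, Hba-a1 −0.067, Cela2a −0.28, and in those 6 libraries with no block acute phase −0.039, drug metabolism −0.037, circadian clock 0.0983, macrophage and Kupffer cell −0.074, endothelial 0.020, Hba-a1 −0.023, Cela2a −0.28. Only genes with 1 coding transcript gave integrated stress response 0.093, unfolded protein response −0.021, periportal hepatocyte −0.043, endothelial −0.0084. With 1 library left out the ranges were Cela2a −0.087 to 0.63, Hba-a1 −0.013 to 0.40, NRF2 targets −0.013 to 0.083, RNA polymerase I and III subunits −0.0077 to 0.11, acute phase −0.11 to 0.16, circadian clock −0.078 to 0.0997, endothelial −0.0982 to 0.13, mitochondrial DNA-encoded −0.063 to 0.12, periportal hepatocyte −0.067 to 0.033, stellate and fibroblast −0.0017 to 0.36, unfolded protein response −0.11 to 0.053. The cause was not tested. Some uncalled lists passed when 1 library was left out: gluconeogenesis without GFP control replicate 2 (adjusted p = 0.0186), replicate 4 (0.00939), POLR2G replicate 3 (0.0472) or replicate 4 (0.0330). So did heat shock without GFP control replicate 2 (0.0185) or the unnumbered library (0.00154). Female-biased genes passed without GFP control replicate 1 (0.00716), replicate 4 (0.0271), POLR2G replicate 1 (0.0286) or the unnumbered library (0.0204), macrophage markers without GFP control replicate 3 (0.0372), replicate 4 (0.00395), POLR2G replicate 1 (0.0342) or replicate 3 (0.00386). Ketogenesis (0.0133), acute phase (0.0248) and stellate markers (0.0122) passed without GFP control replicate 3, and red blood cell genes without GFP control replicate 4 (0.0465) or POLR2G replicate 3 (0.0322). Heat shock also passed under the replicate block (1.46e-04) and in those 6 libraries with no block (2.38e-04). Female-biased genes passed under the block (0.0266) and gluconeogenesis with no filter (0.0423).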

Other observations

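The 140 genes that DESeq2 called, in 126 of which all libraries of one group lay above all of the other, go beyond the 4 edgeR calls but hold more false calls than the threshold allows for if the simulated data are a guide (34 false of 207 calls), and another split of the libraries gave up to 55. All 140 had an unadjusted edgeR p under 0.05, and the genes named here were chosen after their values were seen. Of the PPARA list 10 members were called, all lower. Lower too were the lipid droplet gene Plin4 (2.33-fold, adjusted p = 0.00132), the acyltransferase gene Acnat2 (3.003-fold, adjusted p = 0.00141), the glycerol kinase gene Gk (1.57-fold, adjusted p = 0.0102), and the endothelial lipase gene Lipg (1.73-fold). Further lower genes were Acat2 of cytosolic acetyl-CoA metabolism (2.76-fold), the desaturase genes Fads1 (1.203-fold), Fads2 (1.28-fold) and Fads3 (1.75-fold), the taurine synthesis gene Csad (2.12-fold) and the glutathione transferase gene Gstt3 (1.72-fold).

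Higher with DESeq2 were several genes of amino acid breakdown: the alanine aminotransferase gene Gpt (1.27-fold, adjusted p = 1.77e-08), Ftcd (1.31-fold, adjusted p = 1.88e-06) and Hal (1.25-fold) for histidine, Ivd (1.22-fold) and Mccc2 (1.16-fold) for leucine. Others were Sardh (1.29-fold) and Dmgdh (1.22-fold) for methylated glycines, Agxt2 (1.31-fold), Acmsd (1.51-fold) and Otc (1.497-fold). In the fixed urea cycle and amino acid catabolism list 3 of 25 members were called, and its score did not differ between groups (exact permutation p = 1), so these genes do not show a shift of the whole list. Also higher were Ghr (1.31-fold), Mup3 (1.47-fold), Mup21 (2.08-fold) and Serpina1e (1.60-fold), while the summed Mup counts did not separate the groups (exact permutation p = 0.114). The genes Dusp1 (2.72-fold), Socs3 (2.01-fold), Phlda1 (2.09-fold), Myc (3.02-fold) and Polr2l (1.36-fold) were higher as well.

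Chosen only after the result was seen were the tests on the lipogenesis and heat shock scores, on single left-out libraries for the PPARA list and on ribosomal protein genes. Whether chance could give the counts was tested over the 35 splits of the 8 libraries into 4 and 4. No other split gave as many genes as the real one with edgeR (4 against at most 1, 1 of 35 splits) or with DESeq2 (140 against at most 55, 1 of 35), the smallest share that 35 splits allow, so no regrouping of the libraries matched either count. Both real counts include the delivered Polr2g, without which edgeR called 1 gene higher and 2 lower. Every other split mixes POLR2G and GFP control libraries, which adds spread to genes that differ between the groups, so part of this contrast comes from the design. Chance cannot be excluded for the count of 6 lists with the preset correlation, since 23 of 35 splits gave as many and one gave 14. For male-biased genes 4 of 35 splits gave as small a camera p (7.03e-07 in the real split, 3.79e-10 in another) and for immediate early genes 4 of 35 as well (4.02e-05 and 5.41e-08), so chance cannot be excluded for either.

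For the fall of the PPARA list, no other split gave as small a camera p (3.08e-17, smallest other 5.56e-11, 1 of 35 splits). That is the smallest share 35 splits allow, and the list had the smallest camera p of the 32 lists, so it argues only weakly against chance. The largest adjusted camera p with 1 library left out was 5.50e-12, which argues against a single library. Without the members that share reads with paralogs the camera p was 1.57e-04 at the preset correlation but 0.0906 with an estimated one (median −0.0959). The summed Cyp4a and Acot genes fell 3.80-fold and 1.94-fold (exact permutation p = 0.0286 each). Reads split among the summed genes do not account for the fall of these sums, if the table holds all of their transcripts. If it holds part of them, reads can leave a sum, and the question stays open. The Acaa1 genes were not summed. Among the 13 members with 1 coding transcript in GENCODE M21 the camera p was 2.29e-06 (median −0.15, unadjusted p = 0.0359 with an estimated correlation). In that fit 4 of them passed over the list alone, all lower. For these 13 a count of part of the transcripts does not account for the fall, if the submitters' annotation, which is not given, also holds 1. Cd36, Cyp4a10, Cyp4a31, Acot1, Acot3, Acot4, Pdk4, Crat and Acaa1a have several coding transcripts and lay outside this test, so for them it stays open. A shorter or weaker fast in the POLR2G animals stays open: it would raise lipogenesis, whose score was −0.20 with an exact permutation p of 0.2. A direct effect of POLR2G on PPARA targets, or one through the hormone and lipid state of the animals, is a hypothesis that may explain the pattern and cannot be told apart from a change in fasting state with these libraries; the same vectors in cultured hepatocytes at a fixed fatty acid supply would separate them.

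Some genes that nearly all cells express have almost no counts in the table, in both groups. If the gene values hold part of each gene's transcripts, for example 1 per gene, such gaps should occur among genes with several annotated coding transcripts and not among genes with 1. Among proteasome subunits and oxidative phosphorylation genes, a set chosen before its values were examined this way, 15 of 51 genes with 2 or more coding transcripts and 0 of 25 with 1 lay under 10 CPM (Fisher's exact p = 0.00156). Among ribosomal protein genes, where the gaps were first noticed, it was 17 of 50 and 1 of 25 (Fisher's exact p = 0.00375). Both go with the explanation, but transcript-level values, which would settle it, were not analysed here, and low values of list members such as Acadm, Plin2 and Cpt2 may then say little about those genes.

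For male-biased genes, whose call was lost with an estimated correlation (adjusted p = 0.496), the largest adjusted p with 1 library left out was 0.0122, without GFP control replicate 3. The camera p of the 6 members without near-identical copies was 0.00516 at the preset correlation and 0.192 with an estimated one. For immediate early genes the largest adjusted p with 1 library left out was 0.00395, but the call was lost with an estimated correlation (adjusted p = 0.496) and among genes with 1 coding transcript (adjusted p = 0.133). The heat shock score, tested as a sign of stress at collection beside the immediate early genes, had a mean of −0.17 in the POLR2G libraries with an exact permutation p of 0.4, which decides nothing. Across 10380 genes, which are not independent, Spearman's rho between log2 fold change and gene span was −0.040, and 25 of the 35 splits gave one at least as large in size (up to 0.167), so fold changes did not follow gene length beyond chance.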
